A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

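RNA of 4 Halobacterium salinarum NRC-1 cultures, 1 for each combination of high or low oxygen with light or darkness, was compared with a common reference RNA on 8 2-colour arrays. Per the labels, replicate 1 of each condition held the culture's RNA in Alexa 532 and replicate 2 held it in Alexa 647, and the arrays were made as dye-flips of 4 samples. The 2 arrays of a culture were therefore treated as 1 replicate. No source says that a condition was grown more than once, so p-values rest on how the 4 cultures differ from an additive pattern and do not measure the spread between repeated cultures of a condition.

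The deposited scanner tables give, per the file headers, spot mean intensity and background median intensity for each dye at a high and a low scanner setting, with no normalization. They also hold a spot confidence score, per the file headers, whose definition is not given in the sources used here. The score was under 50 for 172 to 853 spots per array and channel, and 99.9% to 100% of those spots were brighter than the 90th percentile of their channel, so such scores were read as saturation. The deposited series table holds values that follow the log10 ratio of Alexa 532 to Alexa 647 of the same spots. Set against the raw high-scan ratios in slide order they correlated with r of 0.721 to 0.867 and had slopes of 0.669 to 0.885, with column medians from -0.000257 to 0.0671. Its direction followed from this, while its background correction and centring stay unknown, and it served as an alternative only. The scanner software and array normalization used by the authors are not given in the sources used here.

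High-scan intensities were background-corrected with normexp (offset 50) and normalized within each array by loess in limma 3.58.1 under R 4.3.3. The 4 spots of a feature were averaged, each ratio was turned to culture over reference, and both arrays of a culture were averaged. Control spots were not identified and stayed in. Each feature was fitted with oxygen and light as additive terms (lmFit, eBayes), leaving 1 residual degree of freedom and a prior of 1.49, and features with a Benjamini-Hochberg adjusted p under 0.05 were called. Each SE given is the moderated one of this fit, which draws the variance of a feature towards a value shared by all features. Like the p-values, it does not measure the spread between repeated cultures of a condition. The dependence of the oxygen difference on light has no residual degrees of freedom and was given as values. A feature counted as well above background on an array when at least 3 of its 4 spots exceeded 1.5 times the local background in the culture's channel. It counted as not well above background in a condition when both arrays failed this, and as saturated when at least 2 spots had a low score on both arrays. These limits were set after the columns had been seen. For folP and hisD (oxygen) and folP and hisA (light), dim throughout one level, the bound on the fold was computed. Only that of folP for light lay on the side of the bright level, at 0.27 in log2.

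The platform annotation gave 1 symbol for 532 spots, those of 133 features, and no spot had several. The annotation table of a related strain was not used here, and no coordinates are printed. 24 gene lists were written before the data were examined. Of these, 8 had no named member, 8 had 1 or 2 and 8 had at least 3 and were tested with camera (preset correlation 0.01) among the named genes, with an estimated correlation and fry beside it. The rule for named genes was also fixed then. For oxygen it takes, among features above the 25th percentile of mean intensity, the 12 largest differences per direction that pass the test with one sign in both levels of the other factor and both orientations, with places filled by size among features with one sign in all of these. For light it takes 8 per direction, for the dependence 5 per direction with one sign in both orientations, and up to 4 members of each described list. All places were filled by size, since no feature passed.

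The steps were tested on simulated data with 200 of 2688 features changed in oxygen. The changed features were drawn only from those above the intensity limit of the rule for named genes. In the runs through the array steps, all arrays shared the same mean intensities and the same dye bias. An array with a dim reference or a dye bias of its own was therefore not simulated. With a variance per feature drawn from the prior fitted to the real data, 10 runs through the array steps recovered 5.1% of features changed by 1 in log2 and 83.6% of those changed by 2, with the sign right in 98.5% and 99.8%. Of the calls, 9.67% were false, above the nominal 5%, against 5.33% in 40 runs of the fit alone. A first version drew the noise from the shrunken variances of the fit, which spread less than the prior. It recovered 71.3% and 98.8%, with 11.4% of calls false and up to 64 false calls in a run, and was replaced because it overstated the power. For the lists, only the archaella and chemotaxis list of 9 genes was shifted, by 0.5 in log2, through the fit alone. It was called in 40 of 40 runs, and 1 of 320 unchanged lists was called. The noise was independent between genes, so the power and error rate with correlated genes, smaller lists or smaller shifts were not measured.

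Alternatives fixed before the data were examined covered background correction, normalization, the series table, dim features, the average over spots, each array and each culture left out, the model, an array-level fit with blocks, the list test and a rule of size. With an array left out, the other array of its culture stood alone and carried the dye bias of its orientation in full. Ranges of gene values with an array left out come from these settings and do not separate that bias from the difference. Others were added after seeing the data. They are the low scan with and without normexp, print-block medians, dye-shifted partners of left-out arrays, features with a symbol only, all features as the background for camera, lists of measured genes only, and fits without the high oxygen, light second array.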

Results

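Transcript levels were measured in 4 batch cultures of the haloarchaeon Halobacterium salinarum NRC-1, an extreme halophile that can respire oxygen and can also draw energy from light through rhodopsin pumps. The cultures were grown in rich medium to mid-log phase, 50 mL in flasks of 125 mL. High oxygen cultures were shaken at 210 rpm and low oxygen cultures at 100 rpm with the flask stoppered. Each oxygen level was combined with light or with darkness, for which the flask was painted. RNA of each culture was hybridised on 2 spotted 2-colour arrays against a common reference, RNA of a mid-log culture at an OD600 of 0.5 to 0.6, with the dyes exchanged between the arrays. The 8 arrays therefore stand for 4 cultures, 1 per condition, and the pair of arrays of a culture was counted as 1 replicate. Each array carried 10752 spots, 4 for each of 2688 features. Of the features, 133 were named by a gene symbol and 2555 were unnamed here.

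The brightness of the arrays differed. Between 40.7% and 65.3% of features were well above background in the channel that held the culture's RNA. The reference channel was well above background for 665 features on the high oxygen, light replicate 2 array and for 1005 to 1760 on the other arrays. Of the 133 named genes, 70 were measured in all 4 conditions, 26 were saturated in at least 1 condition and 37 were not well above background in at least 1. Background was judged in the culture's channel only, so a gene counted as measured could have a dim reference. On the high oxygen, light replicate 2 array 75.3% of all features had one. Which of the 70 genes this affected was not listed. Arrays of one dye orientation from different cultures correlated across features with r between 0.34 and 0.81. After every ratio had been turned to culture over reference, the pair of arrays of a culture correlated with r of -0.34 for high oxygen in light, -0.08 for high oxygen in darkness, -0.23 for low oxygen in light and -0.12 for low oxygen in darkness. These correlations are across features, which are not independent replicates.

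**Figure D1:**
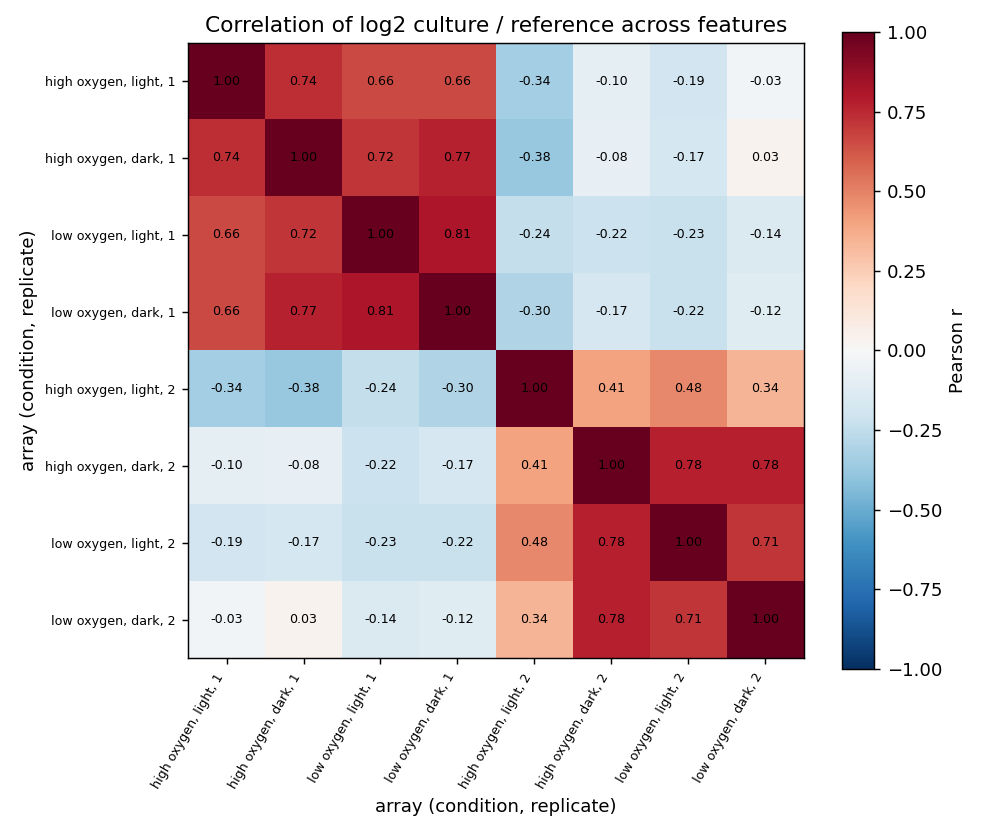
Pearson correlation of the log2 ratio of culture to reference across 2688 features, for each pair of the 8 arrays, ordered by dye orientation (replicate 1, culture RNA in Alexa 532, then replicate 2, culture RNA in Alexa 647). Arrays of one orientation correlate between 0.34 and 0.81, and the arrays of one culture between -0.34 and -0.08.

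The first comparison asked which transcripts differed between high and low oxygen. Among the named genes, gdhA1, a glutamate dehydrogenase, had a log2 difference of -0.37 (SE 0.11, n = 4 cultures), 1.29-fold lower at high oxygen. Each SE here is moderated towards a spread shared by all features and does not measure the spread between repeated cultures. carB, the large subunit of carbamoyl-phosphate synthase, had a difference of -0.22 (SE 0.08). argH, argininosuccinate lyase of arginine synthesis, had a difference of 0.22 (SE 0.08), 1.16-fold higher at high oxygen. It ranged from 0.04 to 0.39 with an array left out, where the other array of that culture stood alone with its whole dye bias. The rule that named these genes required one direction in light, in darkness and in both dye orientations, so that agreement is not separate evidence. None of these genes passed the test: limma called 0 of 2688 features for oxygen, with a lowest adjusted p of 0.839. In the low scan with normexp, a setting added after seeing the data that put the median of all features at 0.28 (-0.04 in the main setting), gdhA1 and carB lay -0.10 each from that median and argH -0.03.

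For argH the difference was 0.17 in light and 0.26 in darkness, for gdhA1 -0.50 and -0.24, and for carB -0.25 and -0.18. Other measured genes on the low side at high oxygen were pan1, a proteasome-activating nucleotidase, at -0.33 (SE 0.17), hisB of histidine synthesis at -0.20 (SE 0.14; 0.02 in the series table and 0.04 in the uncorrected low scan), rpmC, a ribosomal protein, at -0.19 (SE 0.09), cbiT of cobalamin synthesis at -0.18 (SE 0.08) and sucC, a subunit of succinyl-CoA synthetase, at -0.16 (SE 0.09). On the high side were the transducer genes htr6 at 0.15 (SE 0.08) and htr8 at 0.11 (SE 0.08), sop1, sensory rhodopsin I, at 0.11 (SE 0.08; 0.01 without background correction), and uvrB of nucleotide excision repair at 0.10 (SE 0.08; 0.03 with print block medians removed). The values of thrS, gatA, htr2 and secF lay between 0.05 and 0.08, and gatA and htr2 lay below 0 in some of the settings with an array left out. From the median in the low scan with normexp, htr6, htr8, sop1 and uvrB lay between -0.12 and -0.01, secF at -0.23 and hisB at 0.21. With an array left out, htr6 ranged from 0.08 to 0.22, htr8 from 0.04 to 0.19, sop1 from 0.01 to 0.21, uvrB from 0.01 to 0.19, thrS from 0.02 to 0.15, secF from 0.02 to 0.08, hisB from -0.40 to -0.01, cbiT from -0.27 to -0.09, sucC from -0.26 to -0.06 and carB from -0.30 to -0.14. The same rule also named htr7, msrA, trpC, folP, uvrA, mch and hisD, which were not well above background in at least 1 condition, and thiD, which was saturated, so no difference is given for them. Over the named genes, 47 of 133 had one sign in both light levels and both orientations, 15 higher and 32 lower at high oxygen. That share of 35.3% compares with 31.1% over all features and with 33.5% from simulated independent differences with no effect. The real differences were not independent. Between the dye orientations the oxygen differences correlated with r of -0.29 over all features and -0.097 over the named genes, so they did not repeat between orientations.

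**Figure D2:**
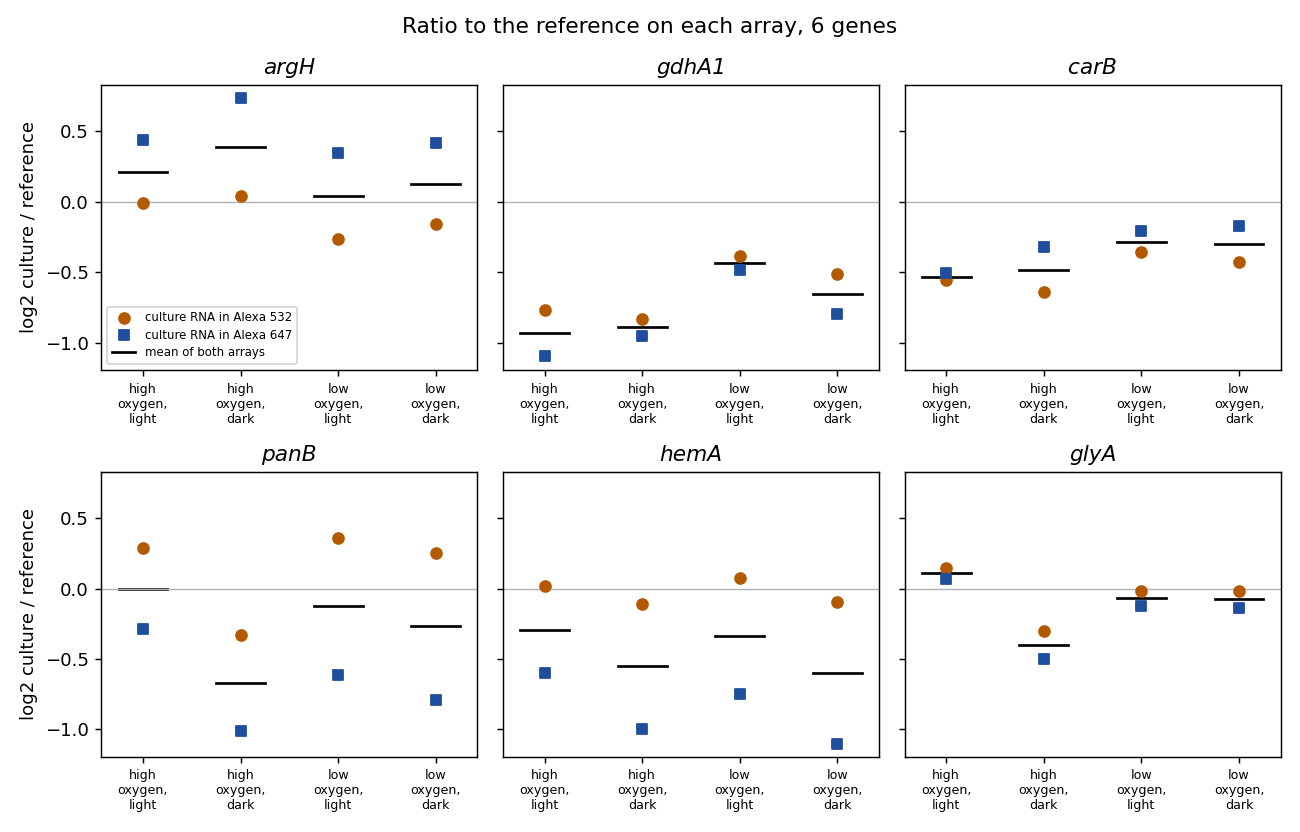
Log2 ratio of culture to reference on each array for 6 named genes. The horizontal axis gives the culture, circles are arrays with the culture's RNA in Alexa 532, squares those with it in Alexa 647, and bars the mean of both. gdhA1 and carB lie lower and argH higher in the high oxygen cultures, and panB and hemA lie higher in the light. For argH, panB and hemA the dye orientations are on average further apart (0.58, 0.82 and 0.83) than the means of the cultures span (0.35, 0.67 and 0.31).

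No gene list was called for oxygen with all named members. With members measured in all conditions only, none of the lists that kept at least 3 members was called. The citric acid cycle, chaperone and proteasome, cobalamin and DNA repair lists kept fewer and were not tested that way. Adjusted p-values below are over all named members of a list, while values and counts of genes are over its members measured in all conditions. The 9 named members of the archaella and chemotaxis list were chemotaxis (che) and transducer (htr) genes, and none was an archaellum gene. Among the 6 measured, 5 were higher and 1 lower at high oxygen. They ranged from -0.15 for htr4 to 0.15 for htr6, with a median log2 difference of 0.07. camera gave this list an adjusted p of 0.155, and an adjusted p of 0.991 with an estimated correlation. Of 5 genes for the other rhodopsins and their transducers, all 4 measured were higher, with a median of 0.06 and an adjusted p of 0.437. Of 5 citric acid cycle genes 3 were saturated, and the measured ones, citZ at -0.04 and sucC at -0.16, were lower (adjusted p 0.728). Of 4 chaperone and proteasome genes the measured ones, dnaK and dnaJ, were at -0.02 and -0.0048 (adjusted p 0.979). The 5 measured of 10 purine and pyrimidine synthesis genes had 2 higher and 3 lower, with a median of -0.04 and an adjusted p of 0.728. The 9 measured of 12 aminoacyl-tRNA synthetase genes had 4 higher and 5 lower, with a median of -0.0026 and an adjusted p of 0.979. Of the cobalamin genes cbiT was at -0.18 and cobN at 0.02, and of the DNA repair genes only uvrB was measured, with the same adjusted p of 0.979 for both lists. Adjusted over each list alone, 0 genes passed in any of these lists.

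Of the lists with fewer than 3 named members, arginine fermentation held arcA at 0.08 (SE 0.08) and arcC at 0.04 (SE 0.08). These genes encode arginine deiminase and carbamate kinase. bat, the regulator of bacterio-opsin, was not well above background. No member of the gas vesicle, DMSO and TMAO respiration, terminal oxidase, ATP synthase, RNA polymerase, general transcription factor, potassium transport or bacterio-opsin activator-like lists was among the named genes, and those groups were not analysed here.

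**Figure D3:**
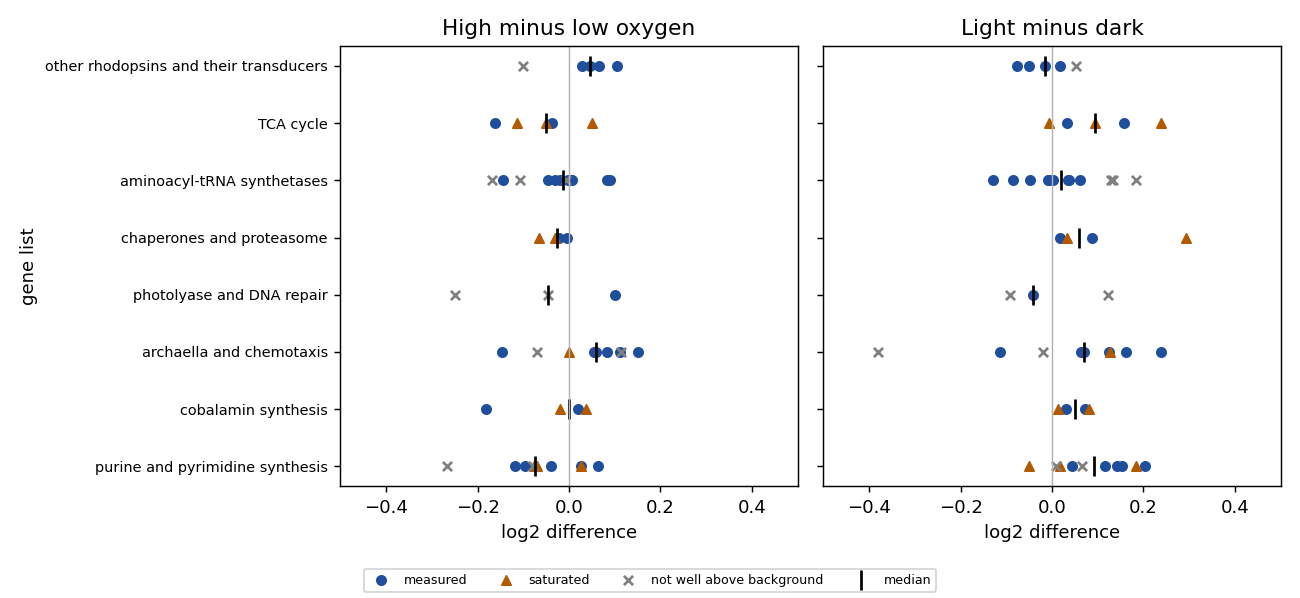
Log2 difference of each named member of the 8 tested gene lists, high minus low oxygen on the left and light minus dark on the right. Circles are genes measured in all conditions, triangles saturated genes, crosses genes not well above background, and vertical marks list medians over all members, which lie between -0.07 and 0.06 for oxygen and between -0.04 and 0.10 for light.

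The absence of calls for oxygen has to be read with the precision of 4 cultures. In simulated arrays with the spread of these data, limma recovered 5.1% of features changed by 1 in log2 and 83.6% of those changed by 2. That spread was drawn with the fitted prior of 1.49 degrees of freedom. The prior was 8.17 with the high oxygen, light replicate 2 array left out, a setting that was not simulated. The changed features were drawn only from those above the intensity limit of the naming rule, so the power for dimmer features was not measured. The simulated arrays shared the same mean intensities and dye bias. They therefore lacked the dim reference of the high oxygen, light replicate 2 array, and the power with such an array was not measured. At an unadjusted p under 0.05 there were 70 features (10 to 228 with an array left out), where chance alone gives 134. The array-level fit gave 254, but it counts both arrays of a culture separately. Their consensus correlation was -0.36, and a negative value narrows the error of differences between cultures. The 254 are therefore not read as an excess over chance. Leaving out the high oxygen, dark culture gave 569 calls, 99.3% of them features with a dim reference on the high oxygen, light replicate 2 array, against 75.3% of all features. Without that array 275 were called, of which 101 were shared.

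The second comparison asked which transcripts differed between light and darkness. panB, an enzyme of pantothenate synthesis, had a log2 difference of 0.41 (SE 0.18, n = 4 cultures; 0.14 to 0.67 with an array left out), 1.32-fold higher in light. hemA, glutamyl-tRNA reductase of haem synthesis, had a difference of 0.26 (SE 0.08; 0.01 to 0.51 with an array left out), with 0.26 at high and 0.26 at low oxygen. infB, a translation initiation factor, had 0.28 (SE 0.14; 0.15 to 0.42 with an array left out) and glyA, serine hydroxymethyltransferase, 0.26 (SE 0.18). limma called 0 of 2688 features for light, with a lowest adjusted p of 0.689. In the low scan with normexp, which put the median of all features at -0.31, panB lay 0.15, hemA 0.25, infB 0.27 and glyA 0.20 above that median.

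For glyA the difference was 0.51 at high oxygen and 0.01 at low oxygen, and for panB it was 0.67 and 0.14. On the low side in light, the measured genes that the rule named were cca at -0.14 (SE 0.09), argH at -0.13 (SE 0.08), aspS at -0.13 (SE 0.08), menD at -0.12 (SE 0.09), arcC at -0.12 (SE 0.08) and htr6 at -0.11 (SE 0.08). The rule left out pan1 at -0.22 (SE 0.17) and gdhA2 at -0.12 (SE 0.12), whose signs differed between the oxygen levels. In at least 1 setting with an array left out cca, argH, aspS and arcC lay above 0, as cca did in the uncorrected low scan. With an array left out htr6 ranged from -0.19 to -0.04, and menD ranged from -0.16 to -0.01 over the processing alternatives other than the low scan with normexp. From the median in the low scan with normexp argH lay 0.12 and aspS 0.18 above. folP, hisA, htr18 and trpC were not well above background in at least 1 condition, and psmA and sdhC were saturated. One sign in both oxygen levels and both orientations was seen for 53 of the 133 named genes, 39 higher and 14 lower in light. That share of 39.8% compares with 41.9% over all features and 33.5% in the simulation of independent differences. Between the dye orientations the light differences correlated with r of 0.27 over all features and 0.19 over the named genes.

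No list was called for light with all named members. With measured members only, none of the lists that kept at least 3 members was called, and the same lists as for oxygen kept fewer and were not tested that way. All 5 measured purine and pyrimidine synthesis genes were higher in light, with a median of 0.14 and an adjusted p of 0.623 for the list of 10. Of 5 citric acid cycle genes 3 were saturated, and citZ was at 0.03 and sucC at 0.16 (adjusted p 0.623). The measured rhodopsin and transducer genes had 1 higher and 3 lower, with a median of -0.03 and an adjusted p of 0.623. Of the 6 measured chemotaxis and transducer genes of the archaella and chemotaxis list, 5 were higher (camera adjusted p 0.864 for the list). Among them was cheY, the chemotaxis response regulator, at 0.24 (SE 0.15). dnaK was at 0.09 and dnaJ at 0.02 (adjusted p 0.638 for the chaperone and proteasome list). The 9 measured aminoacyl-tRNA synthetase genes had 4 higher and 5 lower, with a median of -0.01, and uvrB of DNA repair was at -0.04, with the same adjusted p of 0.638 for both lists. The cobalamin genes cbiT and cobN were at 0.03 and 0.07 (adjusted p 0.864). With an estimated correlation the adjusted p was 0.89 for each of these lists. Both arginine fermentation genes were lower in light, arcA at -0.08 and arcC at -0.12, and both haem synthesis genes on the metal list were higher, hemA at 0.26 and hemL at 0.11, without passing the test. At an unadjusted p under 0.05 there were 85 features (25 to 313 with an array left out, 238 without background correction), against 134 by chance. The array-level fit gave 330, which has the same limit as its count for oxygen. Leaving out the low oxygen, light culture gave 378 calls, and 0 when the high oxygen, light replicate 2 array was left out too.

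The third comparison asked whether the oxygen difference depended on light. With 1 culture per condition it has no test, and the values describe these cultures. panB had an oxygen difference of 0.13 in light and -0.40 in darkness, glyA 0.18 and -0.33, and cheY 0.28 and -0.11. pan1 went the other way, with -0.57 in light and -0.08 in darkness. The gap between these differences was 0.53 for panB but 0.0046 to 1.05 with an array left out, and in the series table it was 0.20 for glyA (0.50 in the main setting), -0.02 for cheY (0.39) and -0.21 for pan1 (-0.49). In the low scan with normexp, where the median gap of all features was -0.34, panB was at -0.61, glyA at -0.41, cheY at 0.14 and pan1 at -0.16. The rule named these 4 measured genes. It also named folP, dcd, htr18, orc7 and trpC, which were not well above background in at least 1 condition, and psmA, which was saturated. The rule required one sign in both dye orientations, which 49.4% of all features had. That is about the share that independent noise would give, so the agreement is no evidence of a dependence. The difference between the oxygen differences reached 1 in log2 in both dye orientations for 2 features, neither of them named by a symbol and neither well above background in all conditions.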

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

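The test of dye bias was chosen after its result was seen, and the tests of exchanged arrays, of a single noisy array and of a dim reference were set before; the comparison of subsets and scans and both spreads set against the gap were added after. In 4 of the 25 measured genes that the rule named, the effect of one factor had opposite signs at the levels of the other on both arrays. For oxygen these were glyA (0.18 in light, -0.33 in darkness, a gap of 0.50), cheY (0.28 and -0.11, a gap of 0.39) and menD (-0.03 and 0.11, a gap of -0.15). For light it was pan1 (-0.46 at high oxygen, 0.03 at low oxygen, a gap of -0.49). None of these differences was tested. The naming rule shaped this count, since a gene named for a factor could not have opposite signs for that factor. In addition, glyA, cheY and pan1 were among the genes named for the size of their dependence. Among all 70 measured named genes, 8 were opposite for oxygen and 5 for light, where independent noise gives 12.5%.

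The pair of arrays of a culture ranked features differently, with correlations of -0.34 to -0.08 after turning. A dye bias of each probe, shared by the cultures, is a candidate explanation: arrays of one orientation from different cultures correlated at 0.34 or more. Such a bias cancels in the mean of a pair only where it is equal on both arrays. The high oxygen, light replicate 2 array correlated with the others of its orientation at 0.34 to 0.48, and those with each other at 0.71 to 0.78. Full cancellation is therefore not shown for that culture. By the labels both arrays of a culture hold the same RNA, so no biological explanation was tested.

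With the mean of each orientation removed, the pairs of the high oxygen, light and low oxygen, dark cultures opposed each other among features brighter than the median, where this was noticed, at -0.24 each with the crossed pairs at 0.22 and 0.30, and in the low scan at -0.07 and -0.14 with 0.08 and 0.16. Over all features the crossed pairs (0.0037 and 0.11) lay above the pairs (-0.02 and -0.16) in the high scan, where the low oxygen, light pair was at -0.18, and below them in the low scan (-0.01 and -0.18 against 0.08 and 0.0042). With the high oxygen, light culture left out, the low oxygen, dark pair lay below the lower of the others by -0.192, past the bound of -0.1 set before, and the verdict on noise of the high oxygen, light replicate 2 array alone depends on the spread: features drawn again, the spread tried first, gave a 95% interval of -0.25 to -0.13 and would exclude it, while the other pairs differed by 0.217, and this was kept because features of the same arrays are no replicates of a pair. The gap ranged from -0.463 to -0.0972 over 8 sets of features and scans, past the bound in 7 and by more than the other pairs differed in 4, among them the brighter features of the high scan (-0.439 against 0.0117) but not those of the low scan (-0.295 against 0.221). Exchanged second arrays and noise of that array alone cannot be told apart here, since each culture has a single pair. The crossed pairs lie above the pairs among brighter features of both scans but not over all features of the low scan. No culture was regrouped. Under an exchange, the means of both cultures would hold the same RNAs. The oxygen and light differences above would then be opposite in sign and equal in size apart from noise, and would not be separate comparisons. This was not tested.

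The high oxygen, light replicate 2 array had the widest log ratios, with an SD of 1.03 against at most 0.449 on the other arrays. A reference channel near background is a candidate explanation. Among the 665 features whose reference was well above background there, its SD was 0.32, a ratio of 0.944 to the highest of the other arrays, against 2.3 over all features.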

How the results depend on the processing

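The low-scan, print-block, dye-shifted, symbol-only, all-feature and measured-only settings, and those without the high oxygen, light second array, were chosen after seeing the data. limma called 0 features in 31 alternatives for oxygen and 34 for light, every single array left out included and Aquantile, which tests nothing, with 6 to 313 and 16 to 626 features at an unadjusted p under 0.05. With dye orientation as replicate block the array-level fit called 0 for oxygen and 0 for light. Without the high oxygen, light second array it called 15 for oxygen. That fit counts both arrays of a culture separately, with a consensus correlation of -0.36 when all arrays are in. Its calls therefore do not rest on repeated cultures. The size rule picked 2 features for light, probes 4453 and 5363, not well above background.

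Leaving out a culture, with the other factor out of the model and a lone culture assumed to vary like the others, gave 0 to 569 calls for oxygen and 0 to 378 for light. The 569 (without high oxygen, dark) and 378 (without low oxygen, light) arose where the high oxygen, light culture stood alone, and 99.3% and 99.7% of them had a dim reference on its second array, against 75.3% of features. Without that array they became 275, of which 101 were shared, and 0. Without the high oxygen, light culture 14 were called for oxygen; the named one was folP, not well above background.

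Cobalamin synthesis alone was called, in the low scan with normexp, as 1 list for oxygen (down, adjusted p = 1.89e-05, and 0.99 with an estimated correlation) and 1 for light (up, 2.2e-05 and 0.897). That setting put the median feature at 0.28 for oxygen and -0.31 for light. Features whose oxygen differences in light and darkness were at least 1 apart in log2 in both dye orientations, with no test, numbered 2. The count was 0 without background correction, 5 with median centring, 0 in the series table and 1 with the median of spots. In the uncorrected low scan 1 feature passed this limit, and in the low scan with normexp 28 features did. They cannot be counted with an array left out. The cause was not tested.

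In 6 processing alternatives other than the low scan with normexp (Aquantile and the dim filter leave values unchanged), 15 of 16 measured named genes for oxygen and 9 of 10 for light kept their sign. With that setting included they were 12 and 5 as it stands, and 9 and 7 with its values taken relative to its median. hisB turned to 0.0244 in the series table, 0.0446 in the uncorrected low scan and 0.491 with normexp, and cca to 0.025 in the uncorrected low scan. In the low scan with normexp, gdhA1 was at 0.176, carB 0.184 and rpmC 0.201 for oxygen, and panB -0.156, infB -0.0442, hemA -0.0588 and glyA -0.108 for light; relative to its median, 7 of 16 oxygen and 2 of 10 light values were opposite to the main ones. With an array left out, oxygen ranged from -0.0311 to 0.176 for gatA and -0.0325 to 0.165 for htr2, and light from -0.261 to 0.0282 for arcC, -0.307 to 0.043 for argH, -0.297 to 0.0372 for aspS and -0.313 to 0.0300 for cca. In these settings the lone array of a culture carries its whole dye bias, so the ranges do not separate that bias from the difference. Of the 133 named genes, 37 were not well above background in at least 1 condition, and none is given a difference of its own.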

Other observations

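Against the reference culture, 14 named genes had one sign on all 8 arrays in both scans, 11 lower and 3 higher. In the high scan alone this held for 27 of the 133 named genes and for 361 of all 2688 features. For 0 of these features did the mean reach 1 in log2. phoU, a regulator of phosphate uptake, was at -0.78 in log2 over the 4 cultures (SD 0.14), gdhA1 at -0.73 (SD 0.23), rpmC at -0.60 (SD 0.16), carB at -0.40 (SD 0.13) and purL of purine synthesis at -0.40 (SD 0.14). hisI, citZ, gdhA2 and cmk were between -0.27 and -0.21. arcC, carbamate kinase of arginine fermentation, was at 0.38 (SD 0.07) and sop1, sensory rhodopsin I, at 0.28 (SD 0.06). Of the others, gyrB and moaA were not well above background and rpl12p was saturated. All arrays share 1 reference RNA, so these values describe the reference as much as the cultures, and no test was made.

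The unnamed features with the lowest oxygen difference among those measured in all conditions with one sign throughout were probe_353 (1.48-fold) and probe_197 (1.37-fold), and those with the highest were probe_1503 (1.31-fold) and probe_4717 (1.24-fold). For light the lowest were probe_3717 (1.75-fold) and probe_887 (1.26-fold), and the highest were probe_1223 (1.40-fold) and probe_197 (1.45-fold). None of these features passed the test.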
